A study of Mus musculus with 15 samples.

How the data were processed

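Poly(A) RNA was sequenced from 15 cultures of neonatal mouse (C57BL/6) cardiac myocytes, grown on elastic silicone membranes in stretch devices. The samples fall into 5 groups of 3 devices: non-stretched control, and static stretch with its primary axis either transverse or longitudinal to the cells, held for 30 min or 4 h. The primary axis was stretched by 14% and the orthogonal axis by 3.6%, per the labels. The labels describe the 3 devices of a group, named A, B and C, as biological replicates.

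The authors deposited 1 table of 13657 genes for the whole series. Per the file headers, it holds an FPKM value (fragments scaled by transcript length and by mapped fragments) for each gene in each library. Per the file headers, it also holds the authors' group values and, for each stretch group against the control, a log2 fold change, a p-value and a q-value for each gene. The test behind those p-values is not given in the sources used here. In the deposited table the q-value equals the Benjamini-Hochberg adjustment of the p-value within 1% for all 13657 genes. The library kit (Illumina TruSeq, which does not mark the strand) is given per the labels' protocols. TopHat 1.4.1, Cufflinks 2.0.2, FastQC and the mouse build mm9 are named per the submitters' processing notes, which give no order or role. Without strand, reads of overlapping or antisense genes cannot be told apart, so values of genes inside or opposite other genes are uncertain.

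FPKM values carry no read counts, so the absolute depth is unknown and no counting interval is given. The lowest values of genes with few reads step by what 1 read is worth, which gave a relative depth per library: the deepest was the transverse 30 min library A (set to 1) and the shallowest the transverse 30 min library B (0.671), with steps equal within 0.002 on the log2 scale required. No value column of another series was present (0 such columns). Genes are listed at 0 in at least 1 library for 160 genes; of these only values per library or on the log2(FPKM + 1) scale are given.

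Gene positions are those of the deposited table, in mm9. The starts count from 0 in the table: end minus start equalled the span of the gene of the same symbol in GRCm38 for 3165 genes, and end minus start plus 1 did for 303, of 12208 genes compared, so 1 was added to each start. No coordinate of GRCm38 is used. Several small RNA entries span kilobases in the table and therefore do not mark the small RNA itself.

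All tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with the trend and robust options. Genes needed at least 1 FPKM in at least 3 libraries (12114 genes). All 15 libraries entered 1 fit of the 5 group means, with 10 residual degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested within a comparison, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Adjusted p-values below are from this limma fit unless another test is named. The 9 comparisons were each stretch group against control, longitudinal against transverse at each duration, 4 h against 30 min within each axis, and the interaction of axis and duration.

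Before the data were examined, 35 gene lists were fixed for processes that mechanical load or cell composition could touch. Of these, 33 had at least 3 members tested; the erythroid markers had 0 members in the table, and the glial and neuronal markers had 3 in the table and 1 tested, so neither received a set test. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists within a comparison. The genes named below follow a rule also fixed beforehand: in each comparison up to 10 genes per direction with the largest log2 fold change among called genes whose replicate values do not overlap between the groups and whose mean reaches 5 FPKM in at least 1 group (for the interaction up to 5 per direction), up to 4 members of smallest p in each list described, and a fixed set (Nppa, Nppb, Acta1, Myh6, Myh7, Fos, Egr1, Atf3, Ankrd1, Ctgf, Cyr61, Rcan1, Gja1 and 1 gene not reported here). Nppa and Myh6 were not analysed here. Not every gene that the rule gives is named below. Which of them lead a paragraph was chosen after their leave-out values were seen.

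The comparison of the axes used Pearson correlation and covariance of log2 fold changes across genes, beside 100 simulated pairs of unchanged groups that share the 3 controls. The fit was tested on simulated data with independent noise and genes changed by 1.5-fold, 2-fold or 4-fold. At 2-fold it recovered 94.0% of changed genes for transverse 30 min against control and 95.5% for longitudinal 4 h against control. Correlated noise, as in these libraries, is not part of that simulation. Its changed genes were chosen at random among those averaging above 5 FPKM on the log2(FPKM + 1) scale, without small RNA entries. Recovery of genes with lower values was therefore not tested. Alternatives fixed beforehand were a pseudocount of 0.1 FPKM, no filter, a filter at 5 FPKM, quantile normalization, median centring, only the groups compared, limma without trend and robust, the replicate letter as a block, and leaving out each library of the groups compared. Fits without 159 small RNA genes (111 tested), fits with a within-group gradient or the position on it as a covariate, fits of the groups compared with the letter as a block, and fits without a library of the other groups were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.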

Results

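Gene expression was measured in 15 libraries, 3 for each of 5 groups of cultured neonatal mouse cardiac myocytes: non-stretched control, and 30 min or 4 h of stretch applied mainly across (transverse) or along (longitudinal) the cells. The series title states that the response depends on the axis of stretch, so each stretch group was compared with the control, the axes were compared at each duration, and the durations were compared within each axis. Relative sequencing depth ranged from 0.671 to 1, and the correlation of log2 values between pairs of libraries ranged from 0.943 to 0.988. Values are means ± SD with n = 3 libraries per group, and log2 fold changes are given ± SE.

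After 30 min of transverse stretch, and apart from small RNA entries, the immediate early transcription factor genes Fos and Egr1 showed the largest changes. Fos, a subunit of the AP-1 transcription factor (chromosome 12, 86814851 to 86818219), rose from 2.89 ± 0.510 FPKM in control to 63.9 ± 7.38 FPKM, a log2 fold change of 4.06 ± 0.17 (16.7-fold, adjusted p = 5.74e-08). Egr1, a zinc finger transcription factor of the early growth response (chromosome 18, 35020861 to 35024610), rose from 16.9 ± 1.90 to 197 ± 40.7 FPKM, a log2 fold change of 3.45 ± 0.16 (adjusted p = 1.42e-07). The antiproliferative gene Btg2 rose by 2.73 ± 0.17, the stress-responsive factor Atf3 by 2.63 ± 0.36, Fosb by 2.46 ± 0.24, the orphan nuclear receptor Nr4a1 by 2.39 ± 0.17, Ier2 by 2.27 ± 0.10 and Egr3 by 2.26 ± 0.26 on the log2 scale. Cyr61, which encodes a matricellular protein, rose by 2.73 ± 0.42 (adjusted p = 0.0118), and this call was lost without control B, transverse 30 min A or transverse 30 min B (adjusted p = 0.0111 to 0.0708 over the leave-outs). Of the 22 named genes called here, 15 kept the call in each of the 15 leave-outs. Clk1, a kinase that phosphorylates splicing factors, fell by 0.74 on the log2 scale (SE 0.10, adjusted p = 0.00278). Among small RNA entries, Mir3100 differed by 7.39 ± 0.45 (from 0.132 to 210 FPKM), Snora5c by -4.94 ± 0.36 and Mir703 by -0.82 ± 0.09.

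Of the 27 immediate early genes tested, 15 rose, 0 fell and 12 were not called at 30 min of transverse stretch, and 21 rose when adjusted over the list alone. The median was 1.05 log2, with camera adjusted p = 8.72e-75 and adjusted p = 0.000458 with an estimated correlation. Of 17 feedback inhibitors of MAP kinase and calcineurin signalling, 5 rose, 0 fell and 12 were not called, with 6 adjusted over the list alone. Among them the MAP kinase phosphatase gene Dusp1 rose by 1.62 ± 0.12 and Errfi1, an inhibitor of the EGF receptor, by 1.34 ± 0.14 on the log2 scale. The camera call of this list (adjusted p = 9.61e-16) was lost, at adjusted p = 0.0809 with an estimated correlation. Of the 20 cytokine, chemokine and NF-kB response genes, 2 rose, 0 fell and 18 were not called, with 3 adjusted over the list alone: Nfkbiz, an atypical inhibitor of NF-kB, by 0.91 ± 0.13, and the prostaglandin synthase gene Ptgs2 by 2.17 ± 0.34. Their camera call also ended, at adjusted p = 0.621 with an estimated correlation. In all, 38 of 12114 genes changed (35 higher, 3 lower). Of the 33 lists, 16 were called by camera, 1 of them also with an estimated correlation, and 2 by fry. Markers of other cell types had lower medians than control, at -0.22 for endothelial (11 genes), -0.12 for macrophage and leukocyte (14) and -0.11 for fibroblast markers (14), and 0 of their members were called.

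**Figure D1:**
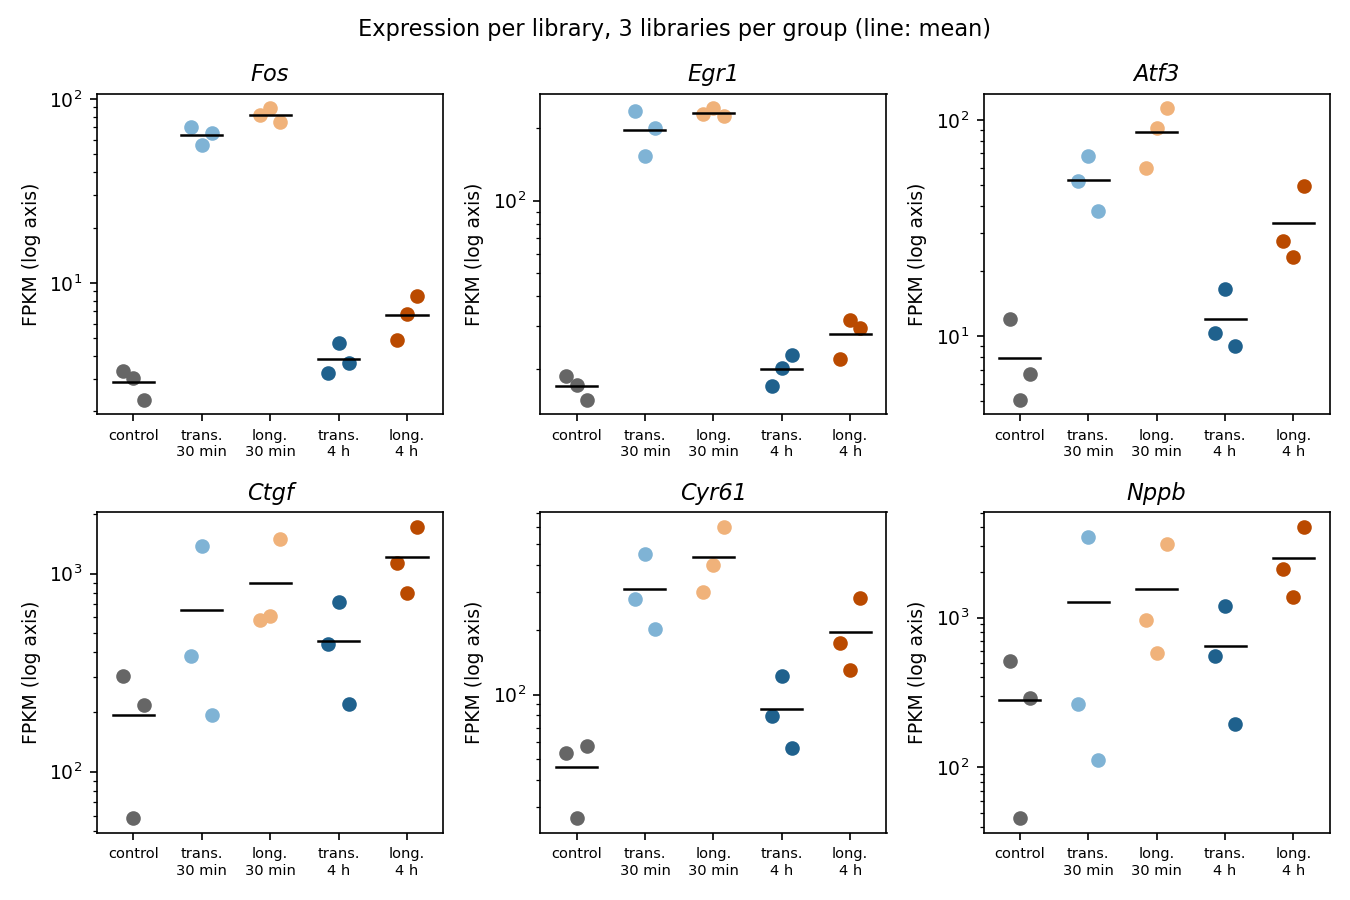
FPKM (log axis) of Fos, Egr1, Atf3, Ctgf, Cyr61 and Nppb in each library, 3 libraries per group, with a line at the group mean. Fos averaged 2.89 FPKM in control and 82.1 FPKM at 30 min of longitudinal stretch, whereas the Nppb values of the 3 libraries of transverse 30 min spread from 112 to 3455 FPKM.

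After 30 min of longitudinal stretch Fos and Egr1 again had the largest changes apart from small RNA entries. Fos rose to 82.1 ± 6.98 FPKM, a log2 fold change of 4.42 ± 0.17 (21.5-fold, adjusted p = 1.19e-08), and Egr1 to 232 ± 9.12 FPKM, a log2 fold change of 3.71 ± 0.16 (adjusted p = 5.83e-08). Atf3 rose by 3.35 ± 0.36, Cyr61 by 3.23 ± 0.42, Btg2 by 2.93 ± 0.17, Fosb by 2.82 ± 0.24, Ptgs2 by 2.71 ± 0.34 and Egr3 by 2.63 ± 0.26 on the log2 scale. Ch25h, the cholesterol 25-hydroxylase, rose by 2.65 ± 0.19 and the cytokine gene Lif by 1.36 ± 0.17, and Ereg, a ligand of the EGF receptor family, rose by 2.25 ± 0.25. Clk1 fell by 0.74 (SE 0.10, adjusted p = 0.00195) and 4933421E11Rik by 0.41 (SE 0.08, adjusted p = 0.0387) on the log2 scale. Among small RNA entries Mir5132 had a log2 fold change of -5.52 ± 0.25, Snora30 one of 4.66 ± 0.85 and Snora34 one of -3.56 ± 0.57. The call of 4933421E11Rik was lost in 10 of 15 leave-outs, all but those of the transverse 30 min libraries, longitudinal 30 min B and transverse 4 h B (adjusted p = 0.0135 to 0.191). That of Snora30 was lost in 12, all but those of longitudinal 30 min C and transverse 4 h B and C (adjusted p = 0.00179 to 0.193). That of Snora34 was lost without control B or C or longitudinal 30 min A or C (adjusted p = 0.00304 to 0.102), and 22 of the 26 named genes called here kept the call in each leave-out. Nppb, which encodes the natriuretic peptide BNP, had a log2 fold change of 2.65 ± 1.30 (adjusted p = 0.582) and Ctgf, a matricellular YAP/TEAD target, one of 2.36 ± 0.79 (adjusted p = 0.42).

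Of the immediate early genes 17 of 27 rose, 0 fell and 10 were not called, with 25 adjusted over the list alone (camera adjusted p = 1.04e-58; adjusted p = 0.00132 with an estimated correlation). Of the feedback inhibitors 6 of 17 rose, 0 fell and 11 were not called, with 9 adjusted over the list alone, among them Errfi1 (1.76 ± 0.14) and Dusp6 (1.48 ± 0.16). Their camera call was lost, at adjusted p = 0.0634 with an estimated correlation. Of 30 secreted growth factor and hormone genes, 2 rose (Ereg and Lif), 0 fell and 28 were not called, with 4 adjusted over the list alone (camera adjusted p = 1.39e-05; adjusted p = 0.741 with an estimated correlation). In all, 54 genes changed (47 higher, 7 lower), and 50 of these were not small RNA entries. Of the 54 genes, 34 were also called at 30 min of transverse stretch, 32 higher and 2 lower in both, against 0.136 and 0.00173 for independent lists. Both comparisons share the 3 control libraries, so part of that overlap may come from them.

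The log2 fold changes of the axes against control correlated across genes with r = 0.587 at 30 min and r = 0.551 at 4 h. Unchanged groups sharing the 3 controls gave a median r of 0.518 in simulation, with 95% of values between 0.0191 and 0.774. The covariance was 0.0475 at 30 min and 0.0643 at 4 h, against a simulated mean of 0.0194, a difference of 0.0281 and 0.0449. In simulation 95% of covariances lay between 0.000694 and 0.0536, so the value at 30 min is within the range of unchanged groups and that at 4 h is above it. At 4 h small RNA entries such as Mir3100 (7.15 transverse, 8.59 longitudinal) and Mir5132 (-5.52 and -5.65) add to the covariance. It was not computed without such entries, so the excess at 4 h may rest in part on them. Genes are not independent replicates. The 3 controls are too few to be split between the axes.

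After 4 h of transverse stretch 7 genes differed from control (1 higher, 6 lower), and 4 of them were small RNA entries. With only the groups compared in the fit it was 16 genes (9 higher, 7 lower), 5 of them shared. Tprkb, a subunit of the KEOPS complex that modifies tRNA (chromosome 6, 85865713 to 85880278), fell by 0.39 on the log2 scale (SE 0.06, adjusted p = 0.0421), from 10.2 ± 0.360 to 7.56 ± 0.123 FPKM. That call was lost in 12 of 15 leave-outs, all but those of transverse 30 min A and B and longitudinal 4 h A (adjusted p = 0.00953 to 0.347). Mir3100 differed by 7.15 ± 0.45, Mir5132 by -5.52 ± 0.25, Mir3101 by -4.86 ± 0.54 and Snora5c by -4.55 ± 0.36 on the log2(FPKM + 1) scale. Fos had a log2 fold change of 0.33 ± 0.17 (adjusted p = 0.516), Egr1 one of 0.22 ± 0.16 (adjusted p = 0.675) and Nppb one of 1.403 ± 1.30 (adjusted p = 0.754). In limma 1288 genes had an unadjusted p under 0.05, against 605.7 expected by chance. Of the 33 lists 6 were called by camera and 0 with an estimated correlation or by fry. The lowest camera p was that of the proliferation genes (24 genes, 0 called, 0 adjusted over the list alone, median -0.33, camera adjusted p = 6.68e-08, adjusted p = 0.873 with an estimated correlation), which include the replication genes Mcm5 (-0.57) and Top2a (-0.45).

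After 4 h of longitudinal stretch 2503 genes differed from control (1249 higher, 1254 lower), most by small amounts: the median size was 0.36 log2, and 274 rose and 178 fell by more than 1.5-fold. Small RNA entries, 12 called higher and 6 lower, had the largest changes among the genes that the naming rule gives. They include Mir3100 (8.59 ± 0.45), Snord72 (7.61 ± 1.71) and Snord34 (-6.52 ± 1.37) on the log2 scale. Cyr61 (chromosome 3, 145309935 to 145312949) rose from 45.8 ± 16.8 to 195 ± 78.2 FPKM, a log2 fold change of 2.07 ± 0.42 (adjusted p = 0.0094). Ptgs2 rose by 1.99 ± 0.34, Atf3 by 1.95 ± 0.36, Ereg by 1.45 ± 0.25 and Fos by 0.97 ± 0.17 on the log2 scale. Ctgf rose from 192 ± 124 to 1218 ± 471 FPKM, a log2 fold change of 2.88 ± 0.79 (adjusted p = 0.0277). Without control B, control C, longitudinal 4 h A or longitudinal 4 h C the call of Ctgf was lost, and over the leave-outs its adjusted p was 0.0128 to 0.104. Of the genes that fell, Ky, a muscle protein linked to kyphoscoliosis in mice, fell by 1.81 (SE 0.34), Smtnl2 by 1.75 (SE 0.31), the histone deacetylase gene Hdac11 by 1.42 (SE 0.28) and the endothelin receptor gene Ednra by 1.38 (SE 0.28) on the log2 scale, with adjusted p of 0.00745, 0.00622, 0.00881 and 0.00881. Nppb had a log2 fold change of 3.57 ± 1.30 (adjusted p = 0.0724), Rcan1, a calcineurin inhibitor, 1.89 ± 0.67 (adjusted p = 0.0658), Ankrd1 1.23 ± 0.51 (adjusted p = 0.0984), Acta1 0.58 ± 0.78, Myh7 -0.19 ± 0.18 and the connexin gene Gja1 -0.08 ± 0.15.

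Of the immediate early genes 15 of 27 rose, 0 fell and 12 were not called at 4 h of longitudinal stretch, with 20 adjusted over the list alone, among them Klf6 (0.93 ± 0.14) and Fosl2 (1.13 ± 0.19). The camera call (adjusted p = 5.08e-10) was lost, at adjusted p = 0.512 with an estimated correlation. Of 17 feedback inhibitors 8 rose, 0 fell and 9 were not called, with 12 adjusted over the list alone, such as Errfi1 (1.17 ± 0.14) and Dusp1 (0.76 ± 0.12), again with adjusted p = 0.512 with an estimated correlation. Of 22 ribosome biogenesis genes 13 rose, 0 fell and 9 were not called, with 15 adjusted over the list alone. They include the nucleolar genes Gnl3 (0.89 ± 0.15), Nolc1 (0.62 ± 0.12), Gar1 (0.60 ± 0.11) and Ddx21 (0.58 ± 0.09). The camera call (adjusted p = 1.36e-07) was lost, at adjusted p = 0.512 with an estimated correlation. Of 25 calcium handling and ion channel genes 7 fell, 0 rose and 18 were not called, with 9 adjusted over the list alone (camera adjusted p = 0.00362; adjusted p = 0.512 with an estimated correlation). These were led by potassium channel genes Kcnj11 (-0.51 ± 0.08) and Kcnh2 (-0.97 ± 0.20). Of 24 YAP/TEAD target genes 7 rose, 1 fell and 16 were not called, with 11 higher and 2 lower adjusted over the list alone, including Cyr61 and the ectonucleotidase gene Nt5e (1.39 ± 0.29). The camera call (adjusted p = 0.0016) ended at adjusted p = 0.542 with an estimated correlation.

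Of 30 extracellular matrix genes 6 rose, 0 fell and 24 were not called, with 6 adjusted over the list alone, such as the thrombospondin gene Thbs1 (1.35 ± 0.20) and the protease gene Adamts1 (1.19 ± 0.16). Camera called this list at adjusted p = 0.000861, and adjusted p = 0.542 with an estimated correlation. Of 15 heat shock genes 4 rose, 0 fell and 11 were not called, with 6 adjusted over the list alone (camera adjusted p = 0.000386; adjusted p = 0.723 with an estimated correlation). Of 24 fatty acid oxidation and mitochondrial biogenesis genes 5 fell, 1 rose and 18 were not called, with the same counts adjusted over the list alone. The gene Slc2a4, encoding the insulin-responsive glucose transporter, fell by 0.60 (SE 0.11) on the log2 scale, and the list was not called by camera (adjusted p = 0.0542). Of 8 ventricular markers 3 fell, 0 rose and 5 were not called, with 4 adjusted over the list alone, including the transcription factor Hey2 (-1.15 ± 0.23). In the set tests camera called it at adjusted p = 0.0417, and adjusted p = 0.53 with an estimated correlation. Of the 26 SRF/MRTF-regulated cytoskeletal genes 5 rose, 1 fell and 20 were not called, with 10 higher and 1 lower adjusted over the list alone (adjusted p = 0.783 with an estimated correlation). Macrophage and leukocyte markers had a median of 0.14 with 0 of 14 called (camera adjusted p = 0.0417, adjusted p = 0.783 with an estimated correlation). Fibroblast markers had 0 of 14 called, and of 11 endothelial markers Flt1 rose (0.62 ± 0.15) and Tek fell by 0.42 (SE 0.13). Of the 33 lists, 15 were called by camera, 0 with an estimated correlation and 8 by fry.

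The number of genes called at 4 h of longitudinal stretch depended on single libraries: 789 without control B, 1034 without control C, 1023 without longitudinal 4 h C and 1429 without longitudinal 4 h A. Of the 99 named genes called here, 40 kept the call in each of the 15 leave-outs. Of the 2503 genes, 94.9% had the same sign at 4 h of transverse stretch, with a median size ratio of 0.372, but the genes were selected on the longitudinal values and the controls are shared. Of the 7 genes called at 4 h of transverse stretch, 6 were among the 2503 (1 higher, 5 lower), against 0.103 and 0.621 for independent lists. The 1 higher is the small RNA entry Mir3100, and the lower ones include Mir5132 and Mir3101. The overlap therefore rests in part on entries whose group and per-library values disagree, as given below.

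**Figure D2:**
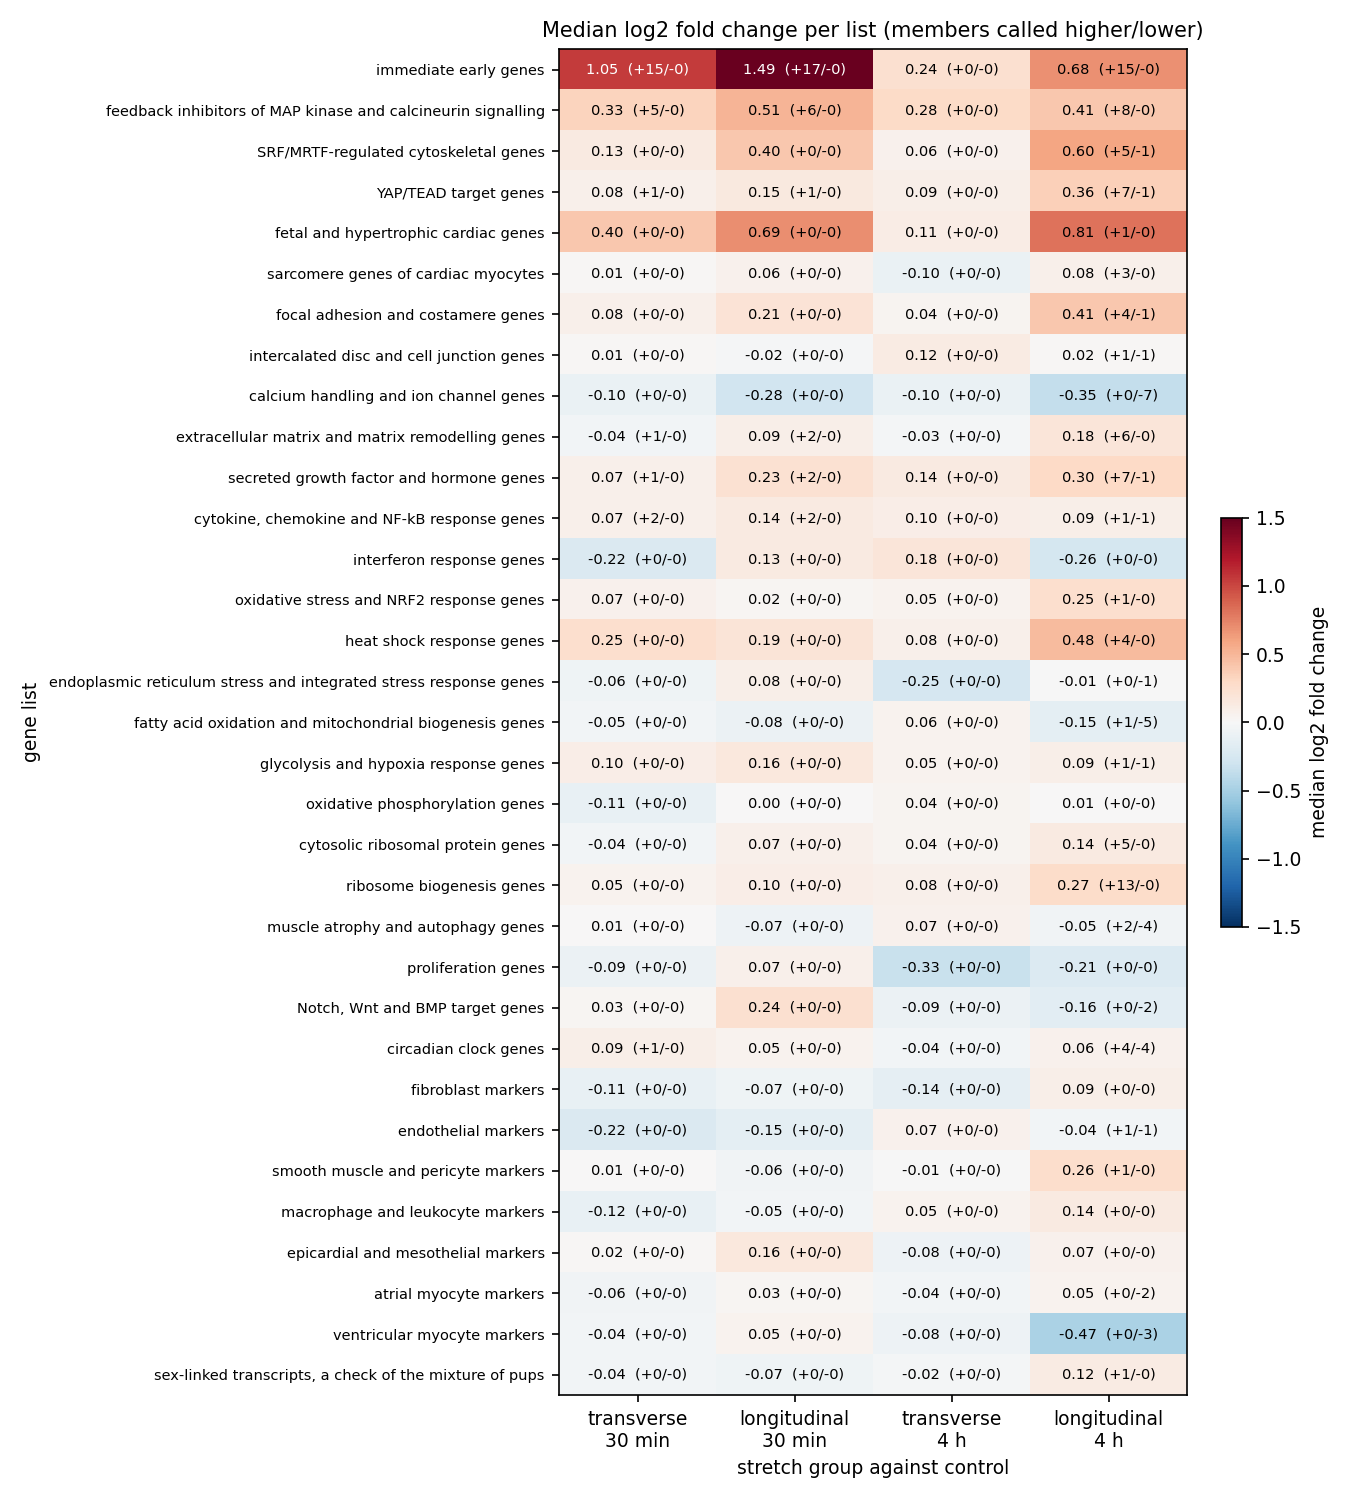
Median log2 fold change against control (colour and number) of the 33 lists with a set test, for the 4 stretch groups, with the number of members called higher (+) and lower (-). Immediate early genes had medians of 1.05 and 1.49 at 30 min of transverse and longitudinal stretch, and 13 ribosome biogenesis genes rose at 4 h of longitudinal stretch.

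The direct comparison of the axes, the question in the series title, called few genes. At 30 min 3 small RNA entries differed: Snora5c was higher under longitudinal stretch by 4.54 ± 0.36, and Mir3100 and Mir5132 were lower, with log2 fold changes of -7.29 ± 0.45 and -5.59 ± 0.25. Fos differed by 0.36 ± 0.17 (adjusted p = 0.804), Egr1 by 0.26 ± 0.16 (adjusted p = 0.809), Atf3 by 0.72 ± 0.36 (adjusted p = 0.804) and Nppb by 1.35 ± 1.30 (adjusted p = 0.827), none of them called. In limma 665 genes had an unadjusted p under 0.05, against 605.7 expected by chance, and without small RNA entries 0 genes were called. The immediate early genes had a median of 0.36 with 0 of 27 called and 0 adjusted over the list alone (camera adjusted p = 1.31e-07; adjusted p = 0.594 with an estimated correlation). Camera called 10 of the 33 lists (8 higher, 2 lower), with 0 called at an estimated correlation and 0 by fry. The count of genes rose to 6 without transverse 30 min A. It rose to 5 without transverse 30 min C, longitudinal 30 min A or transverse 4 h A. In simulated data of this size, with independent noise, changed genes were chosen at random among those averaging above 5 FPKM, without small RNA entries. There 91.0% of 2-fold changes were recovered. That share need not hold for genes of lower values or of wide spread. Nppb, whose spread was wide, differed 2.55-fold here (SE 1.30 log2) and was not called.

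At 4 h 2 genes were higher under longitudinal than transverse stretch: Snora5c by 3.38 ± 0.36 and Gm8615, a predicted gene named here after its values were seen, by 1.83 on the log2 scale (0.0157 FPKM under transverse and 2.65 FPKM under longitudinal stretch). Atf3 differed by 1.38 ± 0.36 (adjusted p = 0.109), Fos by 0.65 ± 0.17 (adjusted p = 0.109), Cyr61 by 1.18 ± 0.42 (adjusted p = 0.132) and Nppb by 2.17 ± 1.30 (adjusted p = 0.299), none of them called. Of the immediate early genes 0 of 27 were called over all genes and 10 rose when adjusted over the list alone (camera adjusted p = 5e-08; adjusted p = 0.452 with an estimated correlation). Of the ribosome biogenesis genes 0 of 22 were called and 14 rose adjusted over the list alone (camera adjusted p = 1.52e-07; adjusted p = 0.452 with an estimated correlation). Of the extracellular matrix genes 0 of 30 were called and 6 rose adjusted over the list alone (camera adjusted p = 1.51e-06; adjusted p = 0.452 with an estimated correlation). Camera called 19 of the 33 lists (14 higher, 5 lower), with 0 called at an estimated correlation and 4 by fry. In limma 3109 genes had an unadjusted p under 0.05, against 605.7 by chance. The count was 173 without transverse 30 min B and 12 without transverse 30 min C, libraries that enter this comparison only through the shared estimate of the spread, and 4 without longitudinal 4 h A or B.

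Between 30 min and 4 h of transverse stretch 41 genes changed (9 higher, 32 lower), and the early genes fell back. Fos fell by 3.74 (SE 0.17, adjusted p = 9.46e-08), Egr1 by 3.23 (SE 0.16), Fosb by 2.50 (SE 0.24), Ier2 by 2.23 (SE 0.10), Btg2 by 2.16 (SE 0.17) and Egr2 by 2.07 (SE 0.21) on the log2 scale. Of the 27 immediate early genes 14 fell, 0 rose and 13 were not called, with 16 adjusted over the list alone (camera adjusted p = 1.22e-30; adjusted p = 0.0179 with an estimated correlation). Of the 34 genes other than small RNA entries that rose at 30 min, 23 were lower at 4 h than at 30 min and 0 were still called above control, their median log2 fold change going from 1.44 to 0.25. Of these 34 genes 33 still had a positive log2 fold change at 4 h, and the authors' deposited table calls Cyr61 at 4 h of transverse stretch (log2 fold change 0.89, q = 0.000366). The genes were selected on the same 30 min libraries, so some of the fall is built in. Clk1 rose again, by 0.58 ± 0.10 (adjusted p = 0.0217), and the actin-binding protein gene Dbn1 rose by 0.40 ± 0.07 (adjusted p = 0.0203). Both calls were lost without transverse 30 min B or C or transverse 4 h C. That of Clk1 was also lost without transverse 30 min A or transverse 4 h A, and that of Dbn1 without transverse 4 h B. Of the 24 named genes called here, 13 kept the call in each of the 15 leave-outs. The count was 25 without transverse 30 min A or transverse 4 h A and 21 without transverse 4 h C.

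Between 30 min and 4 h of longitudinal stretch 603 genes changed (231 higher, 372 lower). Fos fell by 3.45 (SE 0.17), Egr1 by 3.03 (SE 0.16), Ier2 by 2.22 (SE 0.10) and Junb by 1.85 (SE 0.12) on the log2 scale, with adjusted p of 2.51e-07, 6.81e-07, 1.58e-07 and 5.18e-06. Of the 27 immediate early genes 14 fell, 0 rose and 13 were not called, with 15 adjusted over the list alone (camera adjusted p = 6.56e-13; adjusted p = 0.297 with an estimated correlation). Of the 46 genes other than small RNA entries that rose at 30 min, 28 were lower at 4 h than at 30 min and 31 were still called above control, their median going from 1.44 to 0.68, with 45 of the 46 positive and the same selection. The difference from the transverse axis was not called for Fos, Egr1 or Atf3 in the interaction. Of the ribosome biogenesis genes 3 of 22 rose, 0 fell and 19 were not called, with 12 adjusted over the list alone, among them Ddx21 (0.47 ± 0.09) and Gnl3 (0.71 ± 0.15). Their camera call (adjusted p = 3.06e-08) ended at adjusted p = 0.587 with an estimated correlation. The nuclear long non-coding RNA Neat1 rose by 1.32 ± 0.29 (adjusted p = 0.0279), a call lost without longitudinal 30 min A, B or C or longitudinal 4 h A or C (adjusted p = 0.0239 to 0.101). Of the 43 named genes called here, 12 kept the call in each of the 15 leave-outs. The count was 325, 81 and 65 without longitudinal 30 min A, B and C, 97 and 91 without longitudinal 4 h A and C, 383 without control C and 919 without transverse 30 min B. The split of 231 higher against 372 lower became 322 against 292 with quantile normalization and 316 against 307 with median centring.

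The interaction of axis and duration called 3 genes, all higher: Mir3100 (8.73 ± 0.64), Mir5132 (5.46 ± 0.36) and Gm8615 (1.95). Fos had an interaction of 0.29 ± 0.23 (adjusted p = 0.845), Egr1 one of 0.19 ± 0.23 (adjusted p = 0.881), Atf3 one of 0.66 ± 0.51 (adjusted p = 0.838) and Nppb one of 0.82 ± 1.84 (adjusted p = 0.934), so a difference between the axes that changes with time was not detected for these genes. In limma 622 genes had an unadjusted p under 0.05, against 605.7 by chance. Of the 33 lists 15 were called by camera, 0 with an estimated correlation and 0 by fry. The count was 6 without transverse 30 min A and 5 without transverse 30 min C.

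The authors' deposited table calls 53 genes for transverse 30 min (53 higher), 168 for longitudinal 30 min (144 higher, 24 lower), 35 for transverse 4 h (20 higher, 15 lower) and 795 for longitudinal 4 h (495 higher, 300 lower). The fit here also called 27, 39, 1 and 501 of the genes called in the authors' deposited table, each of them in the same direction. Nppb at 4 h of longitudinal stretch has a log2 fold change of 3.17 in the authors' deposited table and is called there, whereas it missed the threshold in the fit here. The authors' deposited table also calls Nppb at longitudinal 30 min (2.48, q = 1.83e-07) and transverse 4 h (1.22, q = 0.00141). It calls Ctgf at longitudinal 30 min (2.21, q = 0.000354) and transverse 4 h (1.25, q = 0.0307). Rcan1 is called there at longitudinal 30 min (1.46, q = 2.08e-06) and 4 h (1.92, q = 8.27e-13). Acta1 is called at transverse 30 min (1.38, q = 0.00697), longitudinal 30 min (1.15, q = 0.000493) and longitudinal 4 h (0.73, q = 0.0271). All of these are uncalled in the fit here.

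Libraries of the same group differed along a gradient of genes, the first principal component of the within-group residuals. It held 54.8% of the within-group sum of squares without small RNA entries, the definition used here, and the first component held 34.7% with them. Nppb moved most, by 4.83 log2 over the range of the 3 transverse 30 min libraries, and other genes near that end include the actin-binding repeat gene Xirp2 (4.05), Ctgf (2.96), Fhl1 (2.93) and the EGF receptor ligand gene Hbegf (2.93). Near its other end were the ephrin gene Efnb3 (-2.33) and Fbxo32, a ubiquitin ligase of muscle atrophy (-1.89). Nppb was at 267, 3455 and 112 FPKM in transverse 30 min A, B and C, at 511, 45.9 and 289 FPKM in the controls and at 2106, 1363 and 4041 FPKM in longitudinal 4 h. Across genes the gradient correlated with the log2 fold changes against control at r = 0.386 for transverse 30 min, 0.626 for longitudinal 30 min, 0.118 for transverse 4 h and 0.725 for longitudinal 4 h. The r was 0.504 and 0.810 for the axes at 30 min and 4 h, -0.246 and 0.384 for 4 h against 30 min transverse and longitudinal, and 0.635 for the interaction.

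**Figure D3:**
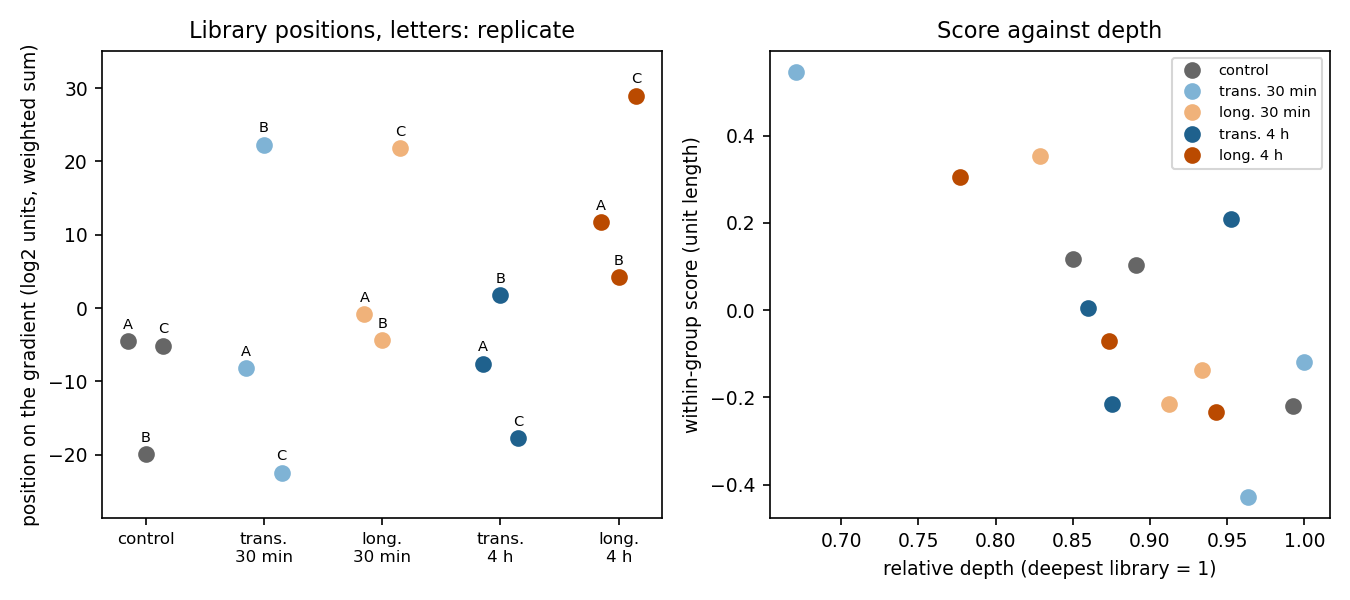
Position of the 15 libraries on the within-group gradient by group (weighted sum of log2 values), and within-group score (unit length) against relative sequencing depth (deepest library set to 1). Transverse 30 min B and C lie at 22.3 and -22.4, and shallower libraries of a group tend to score higher.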

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

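The splits were planned as tests before their results were seen, and the tests of single reads and joint values were chosen afterwards.

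A difference between groups that the series title does not describe was seen for small RNA entries. Between the axes at 30 min Mir3100 had a log2 fold change of -7.29, Mir5132 one of -5.59 and Snora5c one of 4.54. At 4 h Snora5c had 3.38 and the predicted gene Gm8615 1.83. In the interaction Mir3100 had 8.73, Mir5132 5.46 and Gm8615 1.95. Mir3100 was at 0.132 FPKM in control, 210 in transverse 30 min, 0.241 in longitudinal 30 min, 165 in transverse 4 h and 456 in longitudinal 4 h, and Mir5132 was near 60 FPKM in control and transverse 30 min and below 1 FPKM in the other groups.

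Of 83 small RNA entries above 1 FPKM in only some libraries, 5 were above 1 FPKM in all or none of the libraries of every group, against at most 3 in 1000 shuffles of the libraries (median 0). That would follow if the values of a group had been set jointly upstream, and equally if expression switched by group. Gm8615, which is not among these entries, was at 0.0247, 0.0223 and 0 FPKM in transverse 4 h A, B and C and between 2.07 and 3.71 FPKM in all other libraries, so the same doubt holds for it. Poly(A) libraries capture small RNAs poorly, and a few reads over a short transcript give a large FPKM. Of 246 values above 1 FPKM in the 25 small RNA entries called, 70.3% were whole multiples, from 1 to 10, of the entry's lowest value on the scale of 1 read (within 0.02, the lowest value itself counted), short of the 80% set for few reads. In the 3 entries called between the axes, which were tested first, 16 of 25 values (64.0%) were: 9 of 9 for Mir3100, 6 of 6 for Mir5132 and 1 of 10 for Snora5c.

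The authors' deposited table calls 0 small RNA entries in each stretch group. For Mir5132 the authors' deposited table has log2 fold changes of -0.00531 at longitudinal 30 min, -0.0262 at transverse 4 h and -0.47 at longitudinal 4 h. For Mir3100 the authors' deposited table has 2.46 at transverse 30 min, where the fit here has 7.39, with q = 0.99993. The authors' log2 fold change is the log2 ratio of their group values. For Mir5132 the groups of longitudinal 30 min and transverse 4 h thus nearly equal control, while each of their libraries was below 1 FPKM. The group and per-library values of the deposited table disagree for Mir5132, and in size for Mir3100. Sizes also disagree for Snora5c at transverse 4 h (-0.314 in the authors' deposited table, -4.55 in the fit here). Mir3101 has -0.538 there and -4.86 here at transverse 4 h, and -0.556 and -4.86 at longitudinal 4 h. Snora34 has -0.541 there and -3.56 here at longitudinal 30 min. At longitudinal 4 h Snora5c has -1.22 there, so those values do not place it higher than at transverse 4 h. The differences of these entries in the fit here therefore cannot be read as changes in expression. Whether the other differences are biological stays open.

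The interaction also differed between groups for 15 lists called by camera, with 0 members called and estimated-correlation adjusted p between 0.641 and 0.667. Median log2 interactions were 0.11 for immediate early genes, 0.20 for SRF/MRTF-regulated genes, 0.13 for YAP/TEAD targets, 0.35 for fetal and hypertrophic genes, 0.10 for sarcomere genes, 0.19 for focal adhesion genes, 0.11 for extracellular matrix genes and -0.72 for interferon response genes. They were 0.38 for oxidative stress, 0.48 for heat shock, 0.15 for endoplasmic reticulum stress, -0.15 for fatty acid oxidation, -0.15 for oxidative phosphorylation, 0.24 for ribosome biogenesis and -0.44 for ventricular marker genes. Of 100 draws of the grouping, the real one included, 9 gave as many calls as the 3 of the interaction. Chance is therefore not excluded for these 3 calls. The highest other draw gave 991. Draws that exchange labels between axes and durations can carry an axis or duration difference of the real groups, so 991 calls do not show a structure besides them.

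Splits of 3 against 3 libraries number 10, too few for a share under 0.05. Against control, the real grouping gave 38, 54, 7 and 2503 calls for transverse 30 min, longitudinal 30 min, transverse 4 h and longitudinal 4 h, each matched in 1 of 10 splits (the real one) with at most 1 call in the others. The same holds for 4 h against 30 min, with 41 transverse and 603 longitudinal calls, 1 of 10 splits and at most 1 call in the others. Between the axes 2 of 10 splits had as many calls at 30 min (3 calls, highest other 40). At 4 h it was also 2 of 10 (2 calls, highest other 2). The 40 calls of another split at 30 min point to a structure of these samples besides the axis.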

How the results depend on the processing

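The alternatives named as added were chosen after the results were seen; the others were planned. No called named gene result changed its sign in an alternative (0 of 6019 pairs). No list called in the main test was called in the opposite direction by an alternative. Changes of sign among uncalled results were not counted. The balance of higher and lower genes turned in some fits. For 4 h against 30 min longitudinal 231 and 372 became 322 and 292 with quantile normalization and 316 and 307 with median centring. For longitudinal 4 h 1249 and 1254 became, among others, 1111 and 871 with the filter at 5 FPKM and 1314 and 1207 with median centring. For transverse 4 h 1 and 6 became 9 and 7 with only the groups compared. Of 6019 pairs of a called named result and an alternative, 5139 kept the call and 880 lost it. Of the list calls by camera, 110 were lost with an estimated correlation and 94 with fry. With an estimated correlation 1 list each stayed called for transverse 30 min, longitudinal 30 min and 4 h against 30 min transverse. In the other comparisons 0 lists stayed called. FPKM without counts limits what can be said of genes with few reads.

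For longitudinal against transverse at 4 h the count went from 2 to 1 with a pseudocount of 0.1 FPKM and to 1 with the filter at 5 FPKM; at 30 min it went from 3 to 5 without filter. With only the groups compared, which leaves fewer libraries to estimate the spread, the counts were 16 for transverse 4 h and 8 for the axes at 30 min. They were 8 for the axes at 4 h and 20 for 4 h against 30 min longitudinal. For transverse 30 min, longitudinal 30 min and longitudinal 4 h they were 30, 58 and 1969, and 29 for 4 h against 30 min transverse. With the replicate letter as a block they were 1661 for longitudinal 4 h, 27 for 4 h against 30 min transverse and 207 for longitudinal. Only 9 of 30 same-letter pairs of libraries correlated above 0.1 (range -0.502 to 0.513) and 7 of 15 libraries matched their own letter best, so the letter was not used to pair samples. Of the 10 pairs of groups only control with longitudinal 30 min had all 3 letters above 0.1 (0.120, 0.350 and 0.312). Letters A, B and C gave 0.0997, 0.268 and 0.462 between the longitudinal groups. Control with longitudinal 4 h gave -0.00551, 0.306 and 0.257, and the transverse groups 0.00936, 0.425 and 0.513. In the next fits the block raised the counts of the longitudinal groups and not those of the transverse ones. A pairing by letter between some of the groups is therefore not excluded. With only the groups compared and the letter as a replicate block (added) the counts were 18 for transverse 30 min, 69 for longitudinal 30 min, 13 for transverse 4 h, 2243 for longitudinal 4 h, 6 and 7 for the axes at 30 min and 4 h, and 29 and 1146 for 4 h against 30 min transverse and longitudinal. There Nppb at longitudinal 4 h had adjusted p = 0.106 (range over all alternatives 0.000201 to 0.295) and Ctgf adjusted p = 0.0568 (range 3.83e-05 to 0.104), both lowest with the within-group gradient as a covariate. Without small RNA entries (added, fewer genes tested) 2 genes were called for transverse 4 h, 0 for the axes at 30 min, 1 for the axes at 4 h and 1 for the interaction.

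With the within-group gradient as a covariate (added), which takes out spread it was itself computed from and so favours calls, counts rose. They were 94 for transverse 30 min, 886 for longitudinal 30 min, 146 for transverse 4 h, and 4751 for longitudinal 4 h. They were 54 for the axes at 30 min, 3263 for the axes at 4 h, 321 and 2629 for 4 h against 30 min transverse and longitudinal, and 192 for the interaction. With each library's position on it (added) they were 62 for transverse 30 min, 121 for transverse 4 h, 1335 for longitudinal 4 h, and 242 and 1774 for 4 h against 30 min transverse and longitudinal.

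Leaving out each of the 15 libraries in turn (those of other groups added) gave 26 to 36 calls for transverse 30 min, 36 to 70 for longitudinal 30 min, 5 to 10 for transverse 4 h. It gave 789 (control B) to 3249 (transverse 30 min B) for longitudinal 4 h. For the axes it gave 3 (control A) to 6 (transverse 30 min A) at 30 min and 2 (control B) to 173 (transverse 30 min B) at 4 h. It gave 21 (transverse 4 h C) to 44 (transverse 30 min C) and 65 (longitudinal 30 min C) to 919 (transverse 30 min B) for 4 h against 30 min transverse and longitudinal, and 3 (control B) to 6 (transverse 30 min A) for the interaction. The correlation of the axes ranged from 0.590 to 0.646 at 30 min and from 0.525 to 0.622 at 4 h over 3 leave-outs. Except where a construction is named, the cause was not tested.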

Other observations

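The test of other cell types was written before its result, but how its criterion is read was settled after; those of depth and unequal stretch, and the fits with gradient covariates, were chosen after the results were seen.

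Differences between lists along the within-group gradient were not tested. Over the range of the transverse 30 min libraries, the fetal and hypertrophic genes had a median of 1.81 log2 (SE 0.42, 18 genes), SRF/MRTF-regulated genes 0.9969 (SE 0.09, 26 genes), heat shock genes 0.87 (SE 0.33, 15 genes) and sarcomere genes 0.60 (SE 0.14, 19 genes). Growth factor genes had 0.53, proliferation genes 0.36, glycolysis genes 0.33, oxidative stress genes 0.23, smooth muscle and pericyte markers 0.20 (SE 0.41) and endoplasmic reticulum stress genes 0.18. Ventricular markers had -0.49 and ion channel genes -0.43. Hspb1, a small heat shock protein gene, had 2.90 and Lmcd1, a LIM domain gene, 2.91. Among sex-linked transcripts the Y-linked helicase gene Ddx3y was higher at 4 h of longitudinal stretch by 0.57 ± 0.07 (adjusted p = 0.00204), while 4 of the 5 such genes tested were not called.

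Depth was weighed first, since noise of sampling would load on genes with few reads. The median absolute loading of 691 genes of at least 100 FPKM was 1.21 times that of 3440 genes of 1 to 5 FPKM (95% 1.06 to 1.31, 1000 bootstrap draws), but log2(FPKM + 1) shrinks the loadings of low genes, so this decides nothing. With a pseudocount of 0.1 FPKM the ratio was 0.859 (95% 0.761 to 0.938), as depth would give. Any other source of larger spread in low genes would give it too, so the ratio does not single out depth. The shallower libraries of a group also scored higher, at r = 0.805 (exact permutation p = 0.0144 within groups, 7776 permutations, n = 15). Without transverse 30 min A and B it was r = 0.744. The relative depth itself rested on as few as 4 entries in a library (longitudinal 4 h B). Depth may therefore contribute to the gradient, or go along with what made the libraries differ.

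A mix of other cell types, which would move all their markers together and sarcomere genes the other way, was weighed next. Endothelial (0.10) and smooth muscle markers (0.20) lay on the same side as sarcomere genes (0.60), and leukocyte (-0.09) and fibroblast markers (-0.00596) on the other. The medians of the 4 marker lists lay up to 0.290 log2 apart, between smooth muscle and leukocyte markers, which is within the larger of their SE (0.415 and 0.0196). Endothelial and leukocyte markers lay 0.197 apart on both sides of 0, beyond each SE (0.0594 and 0.0196), the only 1 of 6 pairs to do so. The criterion written against a mix was met only by the reading that any such pair decides, which was settled after the values were seen. Fibroblast and smooth muscle markers had SE (0.20 and 0.415) larger than the size of their medians. The test supposes that all other cell types move together, so it cannot exclude a mix in which they differ. A mix of other cells, or a change in a single cell type, stays open.

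Unequal stretch between devices would leave the controls free of the gradient. The leading component of the controls correlated with that of the stretched libraries at 0.123, under the 0.2 set for it, but the SD of the controls on the stretched libraries' gradient was 0.591 times the median of the stretched groups, at or over the 0.5 set against it. The tests disagree, and unequal stretch alone is not settled. With each library's position on the gradient as a covariate, 39.1% of the 2503 longitudinal 4 h calls remained. Their median size went from 0.36 to 0.25 log2 and their median SE from 0.0881 to 0.0811, so calls ended because the folds shrank. The position includes the group means, so it takes out any response along the gradient whatever its source. With the within-group gradient alone as a covariate all 2503 remained, at unchanged folds. Its scores are centred within each group, so it cannot change a fold, and it takes out spread it was computed from. That the calls remained is therefore built in and says nothing about the source, which stays open.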
